A study of Mus musculus with 3 samples.

How the data were processed

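Single-cell RNA sequencing was carried out on mouse orthotopic tumors grown in the cecum from mouse tumor organoids (MTOs, cultured epithelial tumor cells) that had been injected together with colon fibroblasts. There were 3 samples in 3 groups, with 1 sample per group. The fibroblasts were wild type with a guide labelled sgScr (WT sgScr), lacked Prkcz and carried the same guide (Prkcz-/- sgScr), or lacked Prkcz and carried a guide against Sfrp2 (Prkcz-/- sgSfrp2). Tumors were collected 4 weeks after injection, per the labels' protocols. Groups were taken from the genotype label of each sample.

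The material analysed here was a list of cell barcodes and a list of genes for the whole series. Cell Ranger and Seurat, with the mm10 genome build, are named in the submitters' processing notes. Their versions and settings, and the filter that set which barcodes were kept, are not given in the sources used here. The deposited barcode list was text, with a cell barcode of 16 bases and a library suffix (1, 2 or 3) on each line. The deposited gene list was text, with a mouse gene identifier, a symbol and a feature type on each line. Neither list holds a measured value per gene and cell, and UMI counts were not analysed here. Doublets (barcodes that hold more than 1 cell) were neither called nor removed here, since that needs UMI counts, and whether they were removed earlier is not given in the sources used here. The gene levels per cell class, the cell class shares and the processing alternatives planned for them were therefore not run. The sample descriptions end in S1 (WT sgScr), S2 (Prkcz-/- sgScr) and S3 (Prkcz-/- sgSfrp2), the same numbers as the suffixes, but no label says that a suffix follows that number. A suffix can also follow the order in which libraries were combined, so no suffix was assigned to a tumor, and libraries are named below by suffix only.

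Barcodes were counted per suffix. The share of each library among all barcodes was given an exact Clopper-Pearson 95% interval, and each number of shared sequences an exact Poisson 95% interval. These intervals cover counting error only. Read depth per library is unknown from the lists. Sequences were called shared when all 16 bases were identical. The size of the list from which barcodes were drawn was estimated as the number of different starts (first 7 bases) times the number of different ends (last 9 bases), which assumes that every start can occur with every end. Chance sharing was computed from that size and also simulated in 1000 draws of libraries of the observed sizes. Both took every barcode of the list to be equally likely. The counting step was tried on simulated data with 300 sequences planted in all libraries. It recovered a mean of 300.05 over 20 draws, from 300 to 301. At least 300 had to be found by construction. The trial therefore checks neither the estimated list size nor the assumption that all barcodes are used equally.

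Genes of 17 lists were looked up by symbol in the gene list. The lists held fibroblast, Wnt pathway, atypical protein kinase C and SOX genes, and markers of the cell types a tumor could hold. The genes of the series title and genotypes (Prkcz, Sfrp1, Sfrp2 and Sox2) are members of these lists. These lists, the counts of barcodes and of shared sequences and the rule for named genes were fixed before the data were examined. A list size implied by each pair of libraries, the product of their barcode numbers divided by the number shared, was also planned. The estimate of the list size from starts and ends, the simulated draws and the shares of barcodes found in a further library were added after the shared sequences had been counted. Without a count matrix that rule names only the genes of the fixed lists, with Prkcz, Sfrp1, Sfrp2 and Sox2 always named. Positions came from GENCODE M21 (GRCm38, the assembly also called mm10), to which 31011 of the 31053 gene identifiers matched. A gene was scored as overlapped when an exon of another gene on the same strand reached an exon within its last 500 bases. The window was chosen after seeing the gene list. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

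The alternatives tried were to leave out barcodes shared between libraries, to leave out barcodes 1 base from another barcode of the same library, to match barcodes without their last base, to match symbols without regard to case, and to use windows of 200 and 1000 bases.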

Results

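The series addressed the part played by SOX2 and by SFRP1 and SFRP2 in the fibroblasts of intestinal tumors. Its design implied 2 comparisons of orthotopic tumors, each with 1 sample per group. The first set tumors with Prkcz-/- sgScr fibroblasts against tumors with WT sgScr fibroblasts, and bears on the loss of Prkcz, which encodes the atypical protein kinase C zeta. The second set tumors with Prkcz-/- sgSfrp2 fibroblasts against tumors with Prkcz-/- sgScr fibroblasts, and bears on the loss of Sfrp2, which encodes a secreted Frizzled-related protein that binds Wnt ligands. Neither comparison could be made from the lists of barcodes and genes analysed here, since expression values were not analysed and no label states which genotype a library suffix stands for. No statement is made on whether any gene or cell type was higher or lower in any tumor.

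The gene list held 31053 mouse genes, all of a single feature type, gene expression. Of these, 31011 (99.9%) had an identifier in GENCODE M21, including 21974 protein-coding genes, 5459 lincRNA genes, 2816 antisense genes and 13 mitochondrial genes. A symbol was carried by 2 or more identifiers in 35 cases, none of them a gene of the fixed lists.

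The genes named in the title and genotypes were all listed. Prkcz (ENSMUSG00000029053) lies on chromosome 4 from 155260129 to 155361361 on the minus strand of mm10, and spans 101233 bases. Sfrp2 (ENSMUSG00000027996) lies on chromosome 3 from 83766321 to 83774316 on the plus strand. Sfrp1 (ENSMUSG00000031548), a second secreted Frizzled-related protein gene, lies on chromosome 8 from 23411502 to 23449632 on the plus strand. Sox2 (ENSMUSG00000074637), which encodes a transcription factor of stem and progenitor cells, has a single annotated exon on chromosome 3 from 34650405 to 34652461 on the plus strand. The whole of Sox2 lies inside Sox2ot (ENSMUSG00000105265), a noncoding gene on the same strand from 34104270 to 34682619. Sox2ot was not in the gene list, and its exons did not reach the last 500 bases of Sox2. The other gene of the atypical protein kinase C list, Prkci, was also listed.

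The gene groups fixed for the tissue were complete. The list held all 17 fibroblast and cancer-associated fibroblast genes, among them the collagen genes Col1a1, Col1a2 and Col3a1, the platelet-derived growth factor receptor genes Pdgfra and Pdgfrb, and the contractile genes Acta2 and Tagln. It held all 9 genes of secreted Frizzled-related proteins and other Wnt inhibitors, including Sfrp4, Sfrp5, Frzb, Wif1 and Dkk1. The 6 Wnt target and intestinal stem cell genes, such as Axin2 and Lgr5, and the 3 SOX genes were present. Markers of tumor epithelium (6 of 6, such as Epcam and Krt8), fibroblasts (6 of 6), endothelium (5 of 5, such as Pecam1), pericytes (4 of 4), macrophages or monocytes (6 of 6, such as Lyz2), neutrophils (5 of 5), T or NK cells (5 of 5), B or plasma cells (5 of 5), dendritic cells (5 of 5), mesothelium (3 of 3), glia (3 of 3) and erythroid cells (3 of 3) were also present. Over all lists, 87 of 87 different genes were listed. None of the 87 had its last 500 bases overlapped by an exon of another gene on the same strand. Of all listed genes that could be placed, which include noncoding genes, 669 (2.16%) had such an overlap. At so low a share, 0 of 87 does not set the list genes apart, and the difference was not tested. Presence in the list says that a gene could be counted, not that it was expressed.

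The barcode list held 46886 cell barcodes in 3 libraries. Library 1 had 14977 barcodes (31.9% of all, 95% interval 31.5 to 32.4%), library 2 had 14128 (30.1%, 29.7 to 30.6%) and library 3 had 17781 (37.9%, 37.5 to 38.4%). The largest library held 1.26 times as many barcodes as the smallest. The intervals do not overlap, but they cover counting error only. With 1 library each there is no replicate error, and a difference in the number of barcodes between tumors cannot be tested. The extraction protocol states a total of 47153 cells, 267 more than the barcodes listed, at a mean of 18712 reads and 1224 genes per cell.

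The 46886 barcodes comprised 45599 different sequences, of which 969 (2.13%) occurred in more than 1 library. Libraries 1 and 2 shared 699 sequences (95% Poisson interval 648 to 753), against 57.4 expected by chance from a list of 3688320 barcodes (960 starts by 3842 ends). Libraries 1 and 3 shared 453 (412 to 497) against 72.2 expected, and libraries 2 and 3 also shared 453 (412 to 497) against 68.1 expected. In all 3 libraries there were 318 (284 to 355) sequences, against 0.277 expected, and the highest of 1000 simulated draws gave 3. The number of each pair includes these 318. Without them, libraries 1 and 2 shared 381 sequences, libraries 1 and 3 shared 135, and libraries 2 and 3 shared 135. The planned list size, which takes all sharing to be by chance and counts the 318 in every pair, was 302711 barcodes from libraries 1 and 2. It was 587872 from libraries 1 and 3 and 554547 from libraries 2 and 3, all below 3688320. A second comparison did not need the size of the list. Of the barcodes of library 1 that were also in library 2, 45.5% (318 of 699, exact 95% interval 41.8 to 49.3%) were in library 3. Of those not in library 2, 0.946% (135 of 14278, 0.793 to 1.12%) were in library 3. Shared sequences made up 5.57% of library 1, 5.90% of library 2 and 3.31% of library 3.

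**Figure D1:**
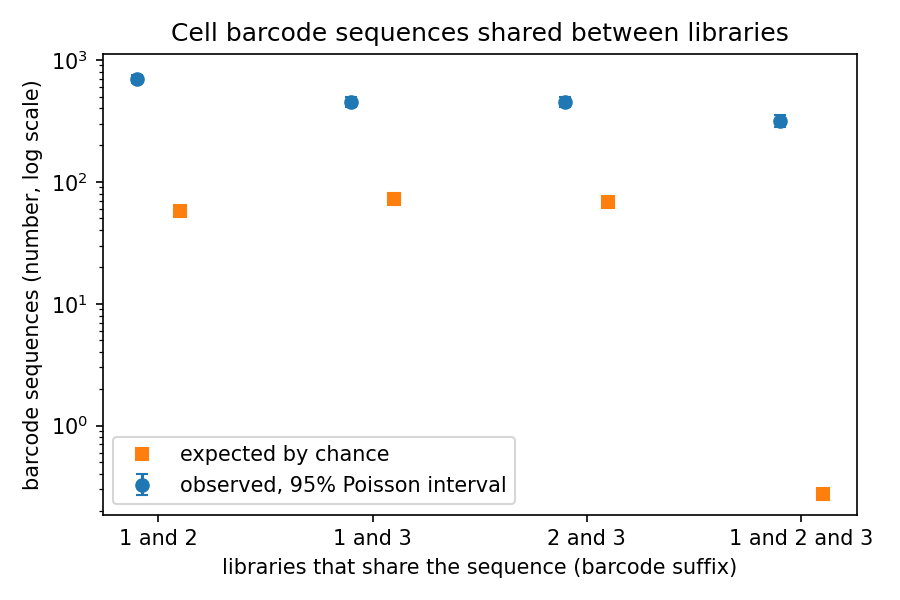
Number of cell barcode sequences (vertical axis, log scale) shared by each set of libraries (horizontal axis, named by barcode suffix). Circles are observed numbers with 95% Poisson intervals, which cover counting error only. Squares are the numbers expected by chance if all barcodes are used equally. For pairs, the observed numbers are 6.27 times (libraries 1 and 3) to 12.2 times (libraries 1 and 2) those expected by chance. For all 3 libraries the numbers are 318 against 0.277. The observed number of each pair includes the 318 sequences found in all 3 libraries.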

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

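Leaving out every barcode whose sequence occurred in more than 1 library lowered the number of barcodes to 14143 in library 1, 13294 in library 2 and 17193 in library 3, because the shared sequences were removed by construction. The order of the 3 libraries by size did not change. Leaving out barcodes 1 base from another in the same library gave 14975, 14126 and 17781. Matching barcodes without their last base gave the same 699, 453, 453 and 318 shared sequences. Every full match stays a match without its last base, so this alternative could hardly have lowered these numbers. Matching symbols without regard to case gave the same 87 genes, which was certain because all 87 had matched exactly. With windows of 200 and 1000 bases, chosen after seeing the data, the number of overlapped list genes stayed at 0. Only the window of 1000 bases could have changed this, because the window of 200 lies inside that of 500. Other settings for cell filters, normalization, low counts and clustering were not run, since UMI counts were not analysed here. No paired analysis was possible because each group had 1 sample. Leaving out a replicate was not possible for the same reason.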

Other observations

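The tests of explanations in this part were chosen after the results were seen. More barcode sequences recurred between libraries than chance draws from one barcode list would give if all barcodes were used equally. The 318 sequences in all 3 libraries were above the highest of 1000 simulated draws (3). Some barcodes being used more often in every library would make library 3, the larger, share at least as many sequences with library 1 as library 2 does. Instead, of the sequences of library 1 that were shared with exactly 1 other library, 26.2% (135 of 516, exact 95% interval 22.4 to 30.2%) were shared with library 3. This is the observed difference itself, with its counting error, set against what the explanation allows. It argues against the same uneven use in every library as the whole cause of the larger overlap of libraries 1 and 2. Uneven use stays open for the 318 sequences in all 3 libraries. It also stays open as part of the sharing between only 2 libraries, since the comparison bears only on the difference between overlaps. For the 969 sequences found in more than 1 library, chance with equal use of all barcodes gives 197 (at most 243 in the simulated draws). Reads or library material crossing between libraries may account for all or part of the excess of 772 over that number. The UMI counts that would decide were not analysed here, and no biological explanation was tested. If some of these shared barcodes are not separate cells, the number of cells would lie below the 46886 barcodes. The reduction would be at most 1287 if each of the 45599 different sequences marks at least 1 cell. That condition was not tested. If about 8000 cells were loaded per library, it could not hold, since each library held more barcodes (14128 to 17781).

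The labels' protocol names version 2 of the 3' kit, whose barcode list, as background knowledge, begins with AAACCTG, while that of version 3 begins with AAACCCA. Of the 46886 barcodes, 0 began with AAACCTG, against a mean of 48.8 barcodes per start over the 960 starts seen, and 44 began with AAACCCA. Barcodes from the list of the kit version in the labels would have given about the mean number, so this argues against that list as the source of these barcodes. The kit that was used, and whether the protocol text was carried over from another experiment, stay open and were not tested.

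The stated mean recovery of 23576 cells fits the stated total of 47153 cells divided over 2.00 libraries, whereas the barcode list has 3 libraries with a mean of 15629 barcodes. The protocol gives about 8000 cells loaded on average, and the libraries held 1.87, 1.77 and 2.22 barcodes per cell loaded. A library cannot hold more separate cells than were loaded. Either that load did not apply to these libraries or not every barcode marked a separate cell, and which was not tested. Doublets among these barcodes were not assessed here.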
